A study of Picosynechococcus sp. PCC 7002 with 11 samples.

How the data were processed

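Gene expression was measured by RNA sequencing in the cyanobacterium Synechococcus sp. PCC 7002, a unicellular marine strain also named Picosynechococcus. Per the labels' protocols, strains grew in A+ HEPES medium under 30% CO2 in a photobioreactor with 1 ng/mL anhydrotetracycline and 5 mM IPTG, the inducers of the constructs, and were harvested in exponential phase at an optical density (720 nm) of 0.3 to 0.6. Total RNA was depleted of ribosomal RNA and sequenced as pairs of 150 bp reads from inserts of about 300 bp.

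The deposited table holds raw counts per annotated feature, made by the authors with STAR 2.7.10b, Subread and featureCounts 2.0.3, per the submitters' processing notes, which give no roles or order. The strand setting, the treatment of reads that map to several places and the genome build were not given in the sources used here. Coordinates are those of the deposited table, whose chromosome is named NC_010475.1 and whose 6 plasmids are named NC_010474.1 and NC_010476.1 to NC_010480.1. Without a stated strand setting, reads of overlapping or antisense features could not be told apart, and counts of near-identical copies (psbA, psbD, apcB, groL, acsF) are uncertain.

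The table has 3277 features, 3271 of the genome and 6 of the introduced constructs. No identifier matched the gene table used for names. Symbols were therefore transferred where replicon, start and end were identical in both, which held for 3144 genome features (96.1%), of which 697 had a symbol. After each of 8 shifts of the coordinates the number of matches was 0. Where several features share a symbol, the end of the locus tag is added (psbA_RS10775). The genes ccmR, ndhF3, ndhF4 and native nhaS3 carried no name in the sources used here, so the targeted genes are not reported by name and the labels were checked only through the construct features.

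The 11 libraries were grouped by their titles into control (3), ccmR knockdown (3), ndhF3 ndhF4 knockdown (2) and nhaS3 overexpression (3, titled nhaS3UTEX overexpression). Nothing in the labels says that replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical. No pair of libraries within a group agreed within sampling noise. Totals ran from 6302775 to 8126405 counts. Intervals and floors cover counting error only.

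Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, the filterByExpr filter, which left 3241 genes, a quasi-likelihood fit of all 11 libraries by group, and Benjamini-Hochberg adjusted p under 0.05. The 6 ribosomal RNA features were left out. Every adjusted p of a gene is from this test unless another tool is named, and standard errors (SE) are the log2 fold change over the square root of F. CPM values were computed with TMM-scaled library sizes. A fold against a group at 0 was bounded with a floor of 3 counts over the group. Lists of genes were tested with camera in limma 3.58.1 (preset correlation 0.01, lists of at least 3 tested members), adjusted over 29 lists. Of these, 7 were the replicons and 22 were among 32 lists fixed before the data were examined. Those lists were fixed by symbols or product words. Apart from stable RNAs and construct parts, members were matched by symbol alone, so features without a symbol are missing. A list can therefore hold only part of the genes it names. Camera compares a list with the other genes.

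The named genes were chosen by a rule fixed before the data were examined. For each strain against control it took the 8 genes of each direction with the greatest log2 fold change among those with a symbol, an adjusted p under 0.05, libraries that did not overlap between the groups and a mean of at least 3 in log2 CPM. It added 2 genes of each direction without a symbol and up to 4 changed members of each list, or the member with the lowest p where none changed. For strain against strain it took 4 genes of each direction. The region that ends at hisA, the runs of neighbouring genes, the row of atp genes and SYNPCC7002_RS17310 were singled out after their values were seen.

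The script was tested on simulated counts of 3220 genes. No change was planted in 3020 of them for the ccmR knockdown, 3021 for the ndhF3 ndhF4 knockdown and 2972 for nhaS3 overexpression. The planted share was thus far smaller than the 38.3% and 36.8% of genes called in the real knockdowns. At a log2 fold change of 1 it recovered 97.1% of changed genes for the ccmR knockdown, 91.4% for the ndhF3 ndhF4 knockdown and 96.3% for nhaS3 overexpression, and at 0.5 it recovered 59.7%, 49.2% and 64.1%.

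Title numbers pair the libraries of control, ccmR knockdown and nhaS3 overexpression, by a rule of correlations over 0.1 in 3 pairs. However, ccmR knockdown replicate 2 correlated better with another number than with its own, both in control and in nhaS3 overexpression. The main test has no term for these pairs. The correlations across genes of deviations from group means were 0.13 to 0.41 for ccmR knockdown with control, 0.13 to 0.44 for ccmR knockdown with nhaS3 overexpression and 0.12 to 0.36 for nhaS3 overexpression with control. The ndhF3 ndhF4 knockdown has 2 libraries and so could not meet that rule (-0.02 to 0.07 with control). Its titles and library names number its libraries differently.

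Alternatives were other scalings, filters, DESeq2 1.42.0, limma-voom, fits of the compared groups alone, replicate blocks, other list tests and leaving out each library. Scaling by total count, leaving out the 3 libraries numbered 3, and leaving out the hisA region with the construct features were added after the data were seen. For the row of atp genes 4 explanations were tried: equal change, a block inside the row, loss of transcript ends and library scaling. The first was excluded by its test, and for scaling only the fold changes with total counts are given. Loss of the hisA region from every copy was first taken as excluded and then as open, and was divided after these values were seen. It is argued against only for members above both limits set by a construct feature that the ccmR knockdown should lack. The number above the limit depends on the limit (8 or 20 of 26). Reads shared with copies elsewhere could also leave counts after full loss, so loss is not excluded for those members. The bounds of the test of a block were set with the fold changes in view and the runs in the ndhF3 ndhF4 knockdown were picked because they fell, so neither outcome is counted in favour of its explanation.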

Results

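The study asked how the cyanobacterium Synechococcus sp. PCC 7002 is affected by very high CO2 and how tolerance can be raised. Transcripts of 11 libraries grown at 30% CO2 were counted: 3 of a control strain, 3 with CRISPR interference against ccmR, 2 with CRISPR interference against the CO2 uptake genes ndhF3 and ndhF4, and 3 overexpressing a heterologous Na+/H+ antiporter, labelled nhaS3UTEX in the titles and called nhaS3 overexpression here. CRISPR interference lowers transcription by directing an inactive Cas protein to a gene. The libraries held 6302775 to 8126405 counts. The transfer-messenger RNA ssrA was the top feature in 10 libraries, at 5.67% to 9.19% of counts. In ccmR knockdown replicate 2 the top feature was psaB, at 5.92%, and stable noncoding RNAs took 3.93% of counts against 7.61% and 8.01% in the other two libraries of that group. The first principal component held 61.3% of the variance and separated both knockdowns from control and nhaS3 overexpression.

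Construct features differed between the groups. KanR, the kanamycin resistance marker, had 28.3 ± 3.98 CPM (SD, n = 3) in the ccmR knockdown and 13.6 ± 0.351 CPM (SD, n = 2) in the ndhF3 ndhF4 knockdown. It had 0 counts in control and nhaS3 overexpression, which makes it at least 198-fold and at least 94.9-fold higher than in control. The first pECA26 feature, pECA26_OE_PP_(pJA0195_g.1, had 12816 ± 971 CPM (SD, n = 3) in nhaS3 overexpression and 0 counts in control, at least 89501-fold higher, and the other two pECA26 features were at least 786-fold and at least 4575-fold higher. No pECA26 feature had more than 8 counts over the libraries of any other group. Both pCas2F features were counted in every library and were lower in the ccmR knockdown than in control, with log2 fold changes of -0.90 (adjusted p = 2.10e-04) and -1.14 (adjusted p = 2.89e-05). SYNPCC7002_RS17310, a genome feature at 2965914 to 2966492 on the chromosome, had 36 to 46 counts in the control libraries and 0 counts in the other 8.

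**Figure D1:**
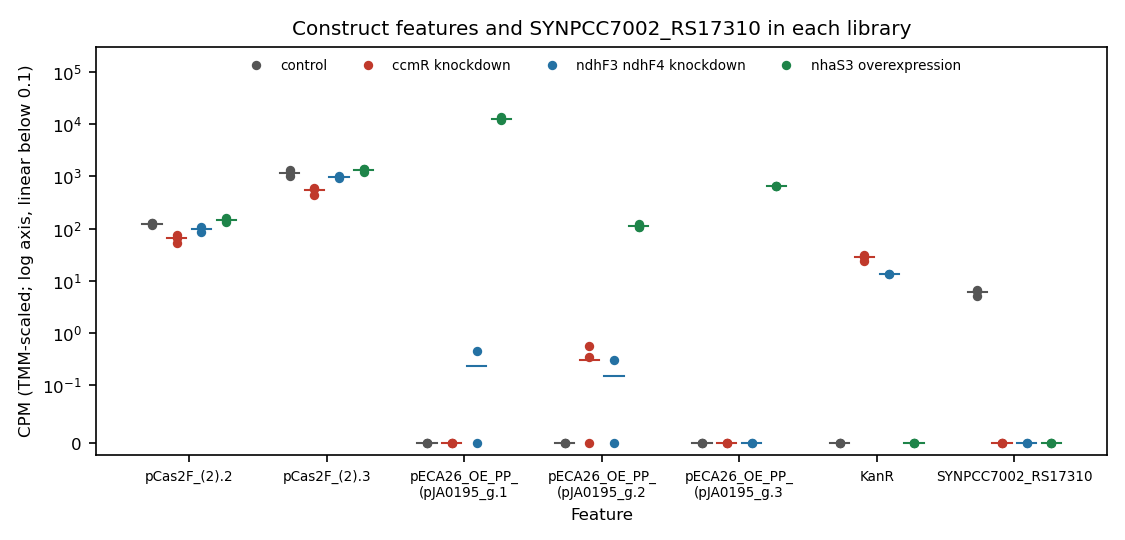
CPM (TMM-scaled, on a log axis that is linear below 0.1) of the 6 construct features and of SYNPCC7002_RS17310, with 1 point per library, a line at each group mean and colours for the 4 groups. KanR is at 0 in control and nhaS3 overexpression, and SYNPCC7002_RS17310 is at 0 in 8 libraries.

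In the ccmR knockdown atpA, psbA_RS10775, acsF_RS03535 and cpcA fell and bicA rose. The gene bicA, a sodium-dependent bicarbonate transporter (2452833 to 2454533), rose from 110 ± 7.93 to 256 ± 60.3 CPM (SD, n = 3 each), a log2 fold change of 1.21 (SE 0.15, adjusted p = 8.95e-05). The circadian clock gene kaiB rose by 0.83 (SE 0.10), and psbN, typA, radC, rpaB_RS02410, ccmA and vapC_RS14815 rose by 0.74 to 1.01. The gene atpA, the alpha subunit of ATP synthase (764678 to 766195), fell from 3941 ± 275 to 546 ± 61.4 CPM, a log2 fold change of -2.85 (SE 0.16, adjusted p = 2.41e-08). The psbA copy psbA_RS10775, which encodes a D1 protein of photosystem II, changed by -2.55 (SE 0.14), acsF_RS03535, an enzyme of chlorophyll synthesis, by -2.33 (SE 0.12), and stpA, an enzyme of glucosylglycerol synthesis, by -1.77 (SE 0.13). Among genes without a symbol and with a mean of at least 3 in log2 CPM, SYNPCC7002_RS09415 (-8.93, SE 0.17) and SYNPCC7002_RS09410 (-8.56, SE 0.25) fell furthest. These 2 overlap each other and lie in the region that ends at hisA. They were at 0.71 to 0.93 and 0.12 to 0.46 CPM in the ccmR knockdown libraries. Their folds thus rest on few counts, at which an SE derived from F is uncertain. Above the same expression limit, the genes without a symbol that rose most were SYNPCC7002_RS03320 (2.19, SE 0.37) and SYNPCC7002_RS03315 (2.18, SE 0.40).

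All 4 tested phycobilisome genes fell, the antenna proteins of light harvesting, with cpcA at -1.78 (SE 0.31), apcB_RS09650 at -1.18, apcD at -0.74 and apcB_RS08170 at -0.59 (4 lower adjusted over the list alone; camera adjusted p = 0.00549, and adjusted p = 0.585 with an estimated correlation). Of 26 photosystem II genes 14 fell and 1 rose (14 and 1 adjusted over the list alone; camera adjusted p = 0.00457, and adjusted p = 0.602 with an estimated correlation), among them psbD_RS10930 at -1.19, psb34 at -1.14 and psbB at -1.12. The median of the photosystem II list was -0.27, and 0.01 with scaling by total count. Of 19 genes of chlorophyll, heme and bilin synthesis 9 fell and 2 rose (9 and 2 adjusted over the list alone; camera adjusted p = 0.0346, and adjusted p = 0.585 with an estimated correlation), with acsF_RS09945 at -1.31 and hemF at -0.79. Of 49 ribosomal protein genes 26 fell and 4 rose, led by rpsU at -0.86 (29 and 4 adjusted over the list alone; camera adjusted p = 1.87e-04, and adjusted p = 0.731 with an estimated correlation). Scaling by total count gave 4 lower and 7 higher ribosomal protein genes.

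Of 10 chaperone genes 5 fell and 2 rose (6 and 3 adjusted over the list alone; camera adjusted p = 0.0636), with groL_RS12190 at -1.09, groES at -1.08, clpB at -0.95 and htpG at -0.88. By replicon, 49 of 108 genes of plasmid NC_010480.1 rose and 1 fell (camera adjusted p = 4.39e-09, and adjusted p = 0.157 with an estimated correlation). On NC_010477.1 11 of 17 genes rose (adjusted p = 1.87e-04; 0.586 as the adjusted p with an estimated correlation) and on NC_010478.1 6 of 31 rose (adjusted p = 0.0170; 0.760 likewise). On NC_010479.1 14 of 42 genes fell (adjusted p = 0.0120; 0.730 likewise) and on NC_010476.1 all 4 fell (adjusted p = 0.0153; 0.585 likewise). The chromosome stood lower than the other genes (524 higher and 596 lower of 2867; adjusted p = 0.00114; 0.0396 likewise). Other lists did not pass: ATP synthase (2 of 6 lower), photosystem I (2 of 6 lower), iron (2 of 4 lower), carotenoid synthesis (2 of 8 lower), cytochrome b6f and electron carriers (1 higher and 2 lower of 10), Calvin cycle (2 higher and 1 lower of 7), nitrogen assimilation (2 higher and 1 lower of 11), glycolysis and the oxidative pentose phosphate pathway (1 of 6 higher), phosphate acquisition (1 of 4 lower), phycobilisome degradation (2 of 3 higher), compatible solutes (1 higher and 1 lower of 4), construct parts (1 higher and 2 lower of 6), stable RNAs (3 higher and 6 lower of 39) and plasmid NC_010474.1 (19 higher and 13 lower of 166). No member passed in glycogen metabolism (4 genes), fermentation (8), cation transport (3) or other NDH-1 subunits (4). Median and mean differed in sign for nitrogen assimilation (-0.11 and 0.01), compatible solutes (0.05 and -0.33) and cytochrome b6f (0.03 and -0.06).

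In all, 1240 of 3241 genes changed in the ccmR knockdown, 610 higher and 630 lower, and 138 of them at least 2-fold. With scaling by total count the median of all genes moved to 0.29 and 85.5% of 1710 calls were higher, against 49.2% with TMM.

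In the ndhF3 ndhF4 knockdown stpA and psbA_RS10775 fell and rimO rose. The gene rimO, which modifies a ribosomal protein (649177 to 650496), rose from 914 ± 40.5 (SD, n = 3) to 2679 ± 16.1 CPM (SD, n = 2), a log2 fold change of 1.55 (SE 0.10, adjusted p = 1.02e-07). The response regulator gene rpaB_RS02410 rose by 1.49 (SE 0.17), pirA by 1.34, ccmA by 1.09 and glmM by 1.03. The gene fbp, a fructose-1,6-bisphosphatase placed by symbol in the list for the Calvin cycle, rose by 0.89 (SE 0.09). Above the limit of 3 in mean log2 CPM, those without a symbol that rose most were SYNPCC7002_RS14830 (3.20, SE 0.11) and SYNPCC7002_RS16570 (2.26, SE 0.18), both on plasmid NC_010480.1. The gene stpA (2964572 to 2965822) changed by -2.36 (SE 0.17, adjusted p = 2.55e-07). It lies next to SYNPCC7002_RS17310, which had 0 counts in the 8 libraries outside control, and stpA was at -0.07 (adjusted p = 0.815) in nhaS3 overexpression. The gene psbA_RS10775 changed by -2.26 (SE 0.16), psbD_RS10930 by -1.37, hisA by -1.21, and crtD of carotenoid synthesis by -0.98. SYNPCC7002_RS09415 (-4.54, SE 0.14) and SYNPCC7002_RS09430 (-4.37, SE 0.19) fell furthest among genes without a symbol above that limit. The catalase-peroxidase gene katG fell by 0.93 (SE 0.10) on the log2 scale, and bicA had a log2 fold change of -0.61 (SE 0.18, adjusted p = 0.0170). The bicA call was lost without ndhF3 ndhF4 knockdown replicate 2 (adjusted p = 0.15), without control replicate 3 (0.051) and with scaling by total count (0.068).

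Of 49 ribosomal protein genes 42 fell and 0 rose, with a median of -0.58 (44 lower adjusted over the list alone; camera adjusted p = 2.00e-11, and adjusted p = 0.629 with an estimated correlation); rpsS was at -0.97, rpsG at -0.84 and rplB at -0.82. Stable noncoding RNAs took 9.24% and 7.65% of counts in these 2 libraries and 6.10% to 6.69% in control. Of 26 photosystem II genes 8 fell and 1 rose (8 and 1 adjusted over the list alone; camera adjusted p = 0.0264, and adjusted p = 0.629 with an estimated correlation), with psbC at -0.99 and psbB at -0.98. On plasmid NC_010480.1 32 of 108 genes rose and 2 fell (adjusted p = 8.58e-04, and adjusted p = 0.629 with an estimated correlation). Lists that did not pass were chaperones (7 of 10 lower), phycobilisome (3 of 4 lower), chlorophyll, heme and bilin synthesis (1 higher and 6 lower of 19, with bchH at 0.83 and hemL at -0.68), carotenoid synthesis (3 of 8 lower), other NDH-1 subunits (2 of 4 lower), iron (2 of 4 lower), phosphate acquisition (1 higher and 2 lower of 4), nitrogen assimilation (1 higher and 3 lower of 11), Calvin cycle (2 higher and 1 lower of 7), cytochrome b6f (1 higher and 2 lower of 10, with petA at -0.87), ATP synthase (1 higher and 1 lower of 6), glycolysis (1 higher and 1 lower of 6), phycobilisome degradation (2 of 3 higher, with nblR at 0.77), photosystem I, glycogen metabolism and compatible solutes (1 lower each), construct parts (1 higher), stable RNAs (2 of 39 lower), fermentation (0 of 8) and cation transport (0 of 3). The chromosome (523 higher and 584 lower) and plasmids NC_010474.1 (13 and 10), NC_010476.1 (0 and 1), NC_010477.1 (2 and 0), NC_010478.1 (3 and 0) and NC_010479.1 (10 and 13) did not pass either. The higher member of the ATP synthase list was atpD_RS15925, at 34.9 and 39.3 CPM against 18.5 to 25.8 CPM in control. It was matched by symbol and lies outside the row of atp genes that holds atpA. Median and mean differed in sign for nitrogen assimilation (0.07 and -0.03), glycolysis (-0.08 and 0.03), NC_010476.1 (0.05 and -0.05), NC_010478.1 (-0.11 and 0.05) and NC_010479.1 (-0.17 and 0.17).

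In all, 1194 genes changed in the ndhF3 ndhF4 knockdown, 584 higher and 610 lower, 139 of them at least 2-fold, and 655 without its replicate 2. With scaling by total count the median of all genes moved to 0.16 and 72.3% of 1249 calls were higher, against 48.9% with TMM.

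**Figure D2:**
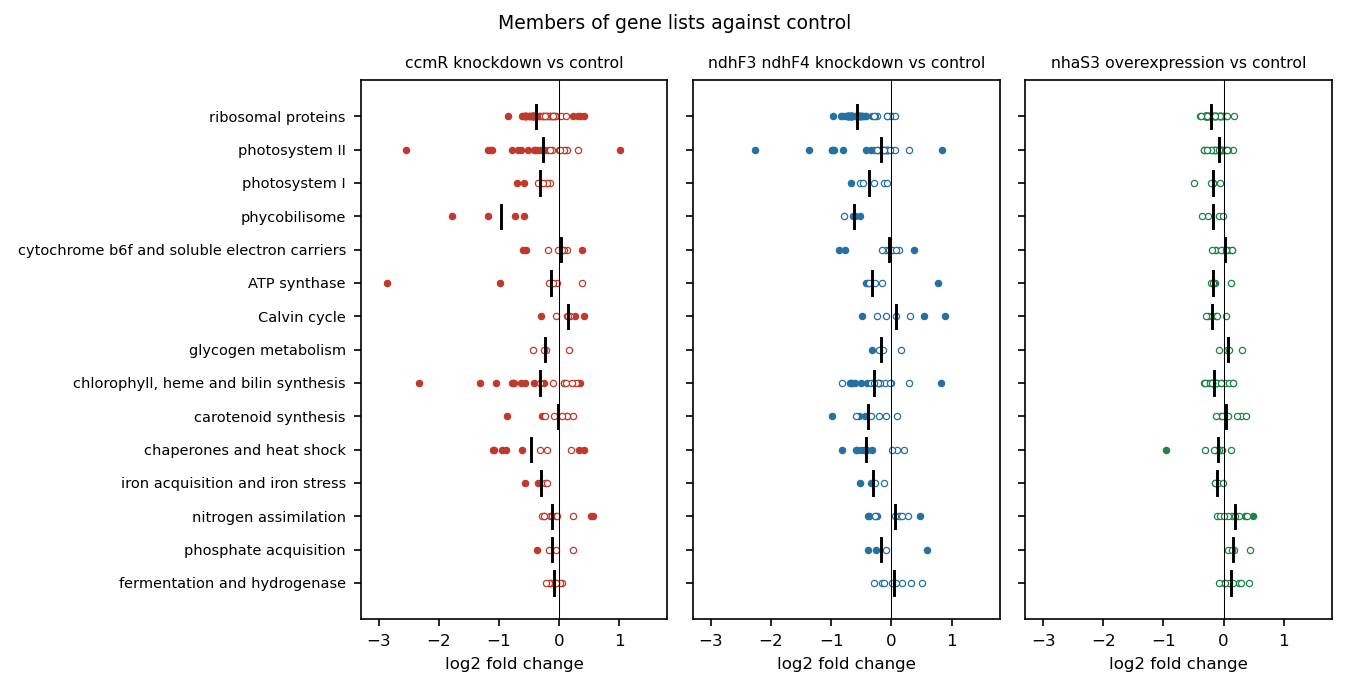
Log2 fold change against control of each tested member of 15 gene lists, in 1 panel per strain; filled points have an adjusted p under 0.05 and black bars are list medians. In the ndhF3 ndhF4 knockdown 42 of 49 ribosomal protein genes are filled, all on the lower side.

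In nhaS3 overexpression clpB fell and SYNPCC7002_RS03205 rose. The gene clpB, a protein disaggregase of the heat shock response (2432148 to 2434742), fell from 900 ± 165 to 461 ± 25.4 CPM (SD, n = 3 each), a log2 fold change of -0.96 (SE 0.14, adjusted p = 0.00148). SYNPCC7002_RS03205 rose by 2.88 (SE 0.09, adjusted p = 4.45e-10) and SYNPCC7002_RS09365 by 1.95 (SE 0.15), while SYNPCC7002_RS01490 changed by -1.93 (SE 0.20) and SYNPCC7002_RS01495 by -1.84 (SE 0.22). Smaller changes were those of accA of fatty acid synthesis (-0.59), ftsH4, a membrane protease (-0.50), pdxA (-0.47) and msrB (-0.38), and of nthB (1.01), nthA (1.00), cas10d (0.71), cas2_RS14395 (0.71) and cas6_RS14410 (0.70) on plasmid NC_010478.1. In nitrogen assimilation 2 of 11 genes rose, glnA, the glutamine synthetase (0.48, SE 0.10), and ntcA, the nitrogen regulator (0.35, SE 0.08); 3 rose adjusted over the list alone (camera adjusted p = 0.0213, and adjusted p = 0.387 with an estimated correlation). Except clpB, each gene with a symbol named here lost its call without at least 1 library, with adjusted p up to 0.15 without nhaS3 overexpression replicate 1 (nthA, cas2_RS14395, msrB), 0.11 without control replicate 1 (cas6_RS14410), 0.074 without nhaS3 overexpression replicate 2 (msrB), 0.079 without its replicate 3 (ntcA), 0.16 without control replicate 2 (cas2_RS14395, msrB) and 0.12 without control replicate 3 (nthA).

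On plasmid NC_010478.1 9 of 31 genes rose, with a median of 0.57 (15 adjusted over the list alone; camera adjusted p = 3.84e-10, and adjusted p = 0.387 with an estimated correlation). Without nhaS3 overexpression replicate 1, where nthA was at 356 CPM against 211 and 175 in the other two, 3 rose and the median was 0.27 (camera adjusted p = 1.87e-06). Without control replicate 2, 1 rose (camera adjusted p = 2.40e-09). Construct parts passed by both (3 of 6 higher, camera adjusted p = 4.40e-12, and adjusted p = 0.00408 with an estimated correlation). The 3 are the pECA26 features of the introduced construct, with 0 counts in control, so this outcome was fixed by the strain itself. Ribosomal protein genes had 0 calls and a median of -0.21 (camera adjusted p = 3.74e-07, and adjusted p = 0.583 with an estimated correlation). Camera also passed plasmids NC_010477.1 (1 of 17 higher; adjusted p = 2.58e-06), NC_010480.1 (3 of 108 higher; 0.00562), NC_010476.1 (0 of 4 called; 0.0451) and NC_010479.1 (0 of 42 called; 0.0451), the chromosome (37 higher and 29 lower; 0.0284), Calvin cycle, photosystem II and chlorophyll, heme and bilin synthesis (0 called; 0.0352 each) and chaperones (1 of 10 lower; 0.0451). With an estimated correlation these adjusted p were 0.117 to 0.678. The other lists had 0 genes called and did not pass: ATP synthase, carotenoid synthesis, compatible solutes, cytochrome b6f, fermentation, glycogen metabolism, glycolysis, iron, cation transport, other NDH-1 subunits, phosphate acquisition, photosystem I, phycobilisome, phycobilisome degradation and stable RNAs. Plasmid NC_010474.1 had 1 gene higher.

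In all, 83 genes changed, 54 higher and 29 lower, 34 of them at least 2-fold; 505 had an unadjusted p under 0.05. With the title numbers as a replicate block the count was 188, with DESeq2 149 and without the 3 libraries numbered 3 it was 160. It was 45 without nhaS3 overexpression replicate 1, 46 without control replicate 2 and 51 without control replicate 3. Of 97 calls with scaling by total count 75.3% were higher, against 65.1% with TMM.

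**Figure D3:**
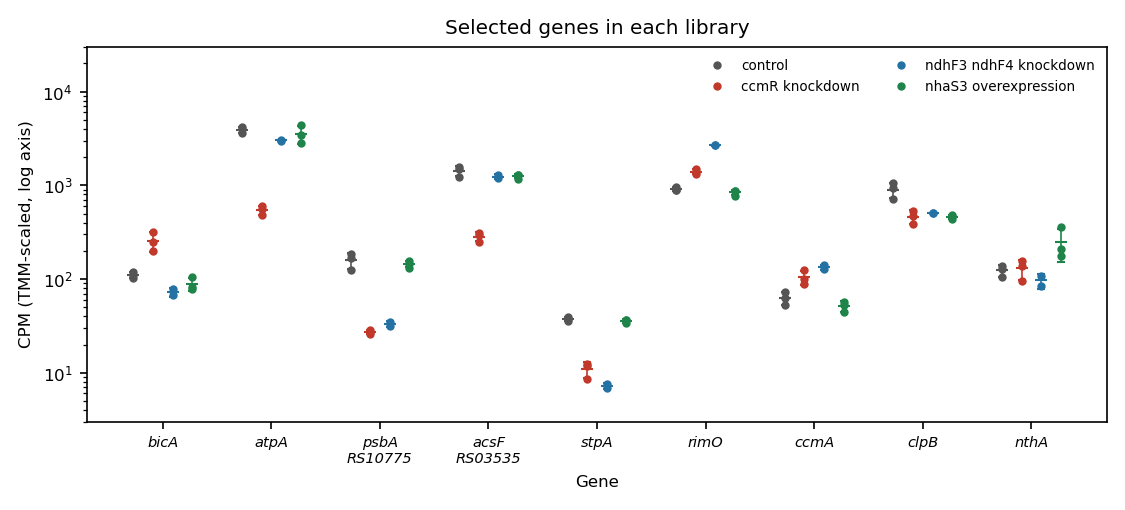
CPM (TMM-scaled, log axis) of 9 named genes, with 1 point per library, dashes at group means and bars of 1 SD, in colours for the 4 groups. The atpA points of the ccmR knockdown lie below all others, and the bicA points of that strain above all others.

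Lists with fewer than 3 tested members had no set test. Of these, ctaD_RS03620 of the respiratory oxidases rose by 0.47 in the ccmR knockdown, katG and trxA were the members for oxidative stress, sigC rose by 0.69 and 0.53 and pilM by 0.37 and 0.58 in the ccmR and ndhF3 ndhF4 knockdowns, and bicA was the 1 member for bicarbonate transport. For both CO2 uptake complexes, the carboxysome, high-light proteins and transposases 0 genes were matched by symbol.

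A region of the chromosome from 1958435 to 1974887, the last of whose 26 features is hisA, changed in all strains. In the ccmR knockdown all 26 fell, with a median log2 fold change of -5.66 (-8.93 to -1.28). In the ndhF3 ndhF4 knockdown 25 fell, with a median of -3.87. In nhaS3 overexpression 17 rose, with a median of 1.23. The 17 features within 10 kb on either side had medians of -0.34, -0.32 and 0.13. Without the region and the construct features the counts of changed genes were 1214, 1161 and 56.

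**Figure D4:**
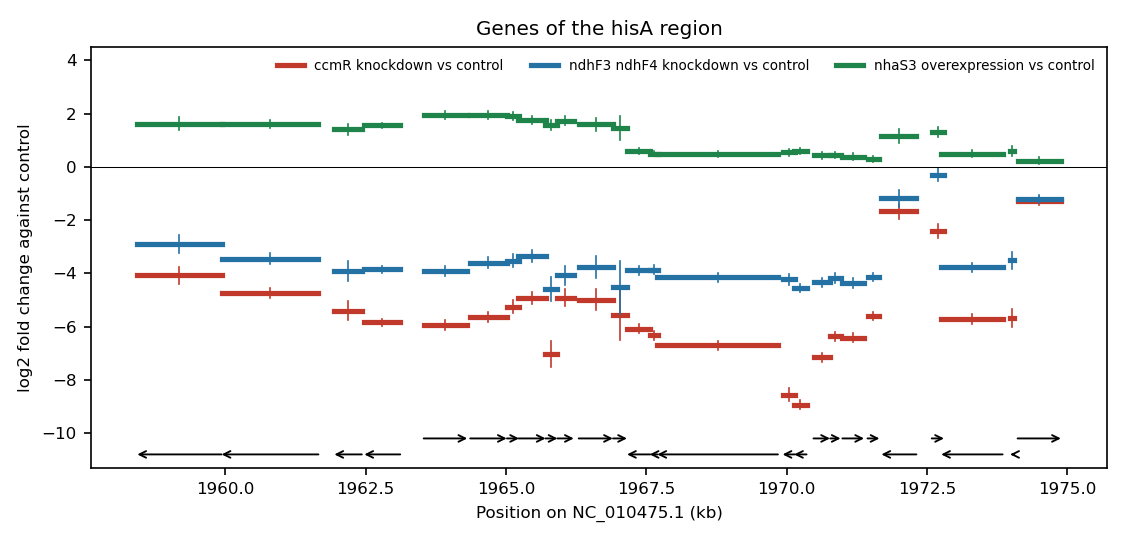
Log2 fold change against control (bars span each gene, thin lines are ± 1 SE) along 1958435 to 1974887 of NC_010475.1, with arrows for the strand. Medians are -5.66 in the ccmR knockdown, -3.87 in the ndhF3 ndhF4 knockdown and 1.23 in nhaS3 overexpression.

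The strains were also compared with each other. Against the ndhF3 ndhF4 knockdown, the ccmR knockdown had higher bicA (1.82, SE 0.18, adjusted p = 1.45e-05), folE_RS12120 (0.87), miaA (0.82) and rpoB (0.80), and lower atpA (-2.47), acsF_RS03535 (-2.12), cysT (-1.57) and pirA (-1.38). The miaA call was lost without ndhF3 ndhF4 knockdown replicate 2 (adjusted p = 0.14). Of 49 ribosomal protein genes 8 were higher (3 adjusted over the list alone; camera adjusted p = 9.62e-05, and adjusted p = 0.939 with an estimated correlation). In all 831 genes differed, 378 higher and 453 lower, 117 at least 2-fold; the count was 457 without ndhF3 ndhF4 knockdown replicate 1 and 328 without replicate 2. With scaling by total count 72.3% of calls were higher, against 45.5%.

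Against nhaS3 overexpression, the ccmR knockdown had higher bicA (1.53, SE 0.16), ccmA (1.03), psbN (0.97) and typA (0.91), and lower atpA (-2.70, SE 0.16), psbA_RS10775 (-2.41), acsF_RS03535 (-2.14) and stpA (-1.70). In all 1435 genes differed, 734 higher and 701 lower, 149 at least 2-fold. The share of higher calls with scaling by total count was 79.8%, against 51.1%. The ndhF3 ndhF4 knockdown had higher pirA (1.90, SE 0.20), rimO (1.67), rpaB_RS02410 (1.46) and ccmA (1.38), and lower stpA (-2.28, SE 0.17), psbA_RS10775 (-2.12), hisA (-1.43) and nthA (-1.36). In all 1251 genes differed, 628 higher and 623 lower, 154 at least 2-fold, and 781 without ndhF3 ndhF4 knockdown replicate 2. The higher share was 66.3% with scaling by total count, against 50.2%.

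Both knockdowns changed 653 genes in the same direction, 296 higher and 357 lower, and 34 in opposite directions. Independent lists would share 110 and 119. Log2 fold changes correlated across genes, which are not independent replicates, at r = 0.74 (0.45 in simulations; rank correlation 0.61), with a covariance of 0.312 against 0.0130 in 50 simulations of unchanged groups with the same controls. Without the region that ends at hisA and the construct features, r was 0.60 (0.45 in simulations), the rank correlation 0.60 and the covariance 0.143 against 0.0130. The controls were too few to be split, so part of the excess may come from them. KanR was counted in both knockdowns and had 0 counts in control and nhaS3 overexpression. Anything that came with that marker therefore cannot be told apart from the knockdowns in what they share. The ccmR knockdown shared 10 higher and 13 lower genes with nhaS3 overexpression, where independent lists would share 10.2 and 5.64, and had 28 opposite, 17 of them in that region. Their r was 0.0032 (0.51 in simulations) and the covariance 0.00068 against 0.0131. The simulations drew each library on its own, without the pairing by title number of the ccmR knockdown, nhaS3 overexpression and control libraries. Without the region and the construct features r was 0.35 (0.51 in simulations), the rank correlation 0.11 and the covariance 0.0467 against 0.0131. The ndhF3 ndhF4 knockdown shared 10 higher and 12 lower genes with nhaS3 overexpression, where independent lists would share 9.73 and 5.46, and had 30 opposite, 16 of them in that region. Their r was 0.087 (0.45 in simulations) and the covariance 0.0161 against 0.0131. Without the region and the construct features r was 0.32 (0.45 in simulations), the rank correlation 0.15 and the covariance 0.0471 against 0.0130.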

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

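The tests of neighbouring genes and of the row of atp genes, and the rule for ribosomal RNA counts, were chosen after the results were seen; the splits of the libraries were planned.

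Genes named in the report that changed in opposite directions in 2 strains, with the difference itself past the test, are given as the difference of log2 fold changes. Between the ccmR and ndhF3 ndhF4 knockdowns it was 1.82 for bicA, -1.69 for SYNPCC7002_RS01490, -2.07 for SYNPCC7002_RS01495, 0.59 for rpmB and -1.57 for cysT. Between the ccmR knockdown and nhaS3 overexpression it was -9.52 for SYNPCC7002_RS09415, -9.10 for SYNPCC7002_RS09410, -7.60 for SYNPCC7002_RS09365 and 0.75 for pdxA. Between the ndhF3 ndhF4 knockdown and nhaS3 overexpression it was -5.13 for SYNPCC7002_RS09415, -4.77 for SYNPCC7002_RS09410, -5.55 for SYNPCC7002_RS09365, -0.60 for ntcA, 2.61 for SYNPCC7002_RS01490 and 2.77 for SYNPCC7002_RS01495. Ribosomal RNA features, left out of the tests, had 632 counts in ccmR knockdown replicate 2 and 207 in ndhF3 ndhF4 knockdown replicate 2, against 124 to 148 in control.

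The first pattern is the fall of neighbouring features in the region that ends at hisA, 26 of 26 in the ccmR knockdown and 25 of 26 in the ndhF3 ndhF4 knockdown. Repression of 1 transcription unit is argued against by the 12 members on the less frequent strand. Loss from part of the copies, as the whole cause, is argued against by unequal falls (Cochran's Q over its degrees of freedom). The value was 81.034 in the ccmR knockdown and 41.076 among the last 15 members in the ndhF3 ndhF4 knockdown. Without SYNPCC7002_RS09440, SYNPCC7002_RS16700 and hisA these values were 28.3 and 2.24. Such loss stays open for the first 11 members in the ndhF3 ndhF4 knockdown, at 1.839. Q treats members as independent, though they share libraries and some overlap. It also uses SE derived from F, which is uncertain at few counts, so its size is approximate. Loss from every copy, as the whole cause in the ccmR knockdown, is argued against for 8 members by their residual (a share of the higher of control and nhaS3 overexpression). It lay above 1.19%, the upper 95% limit for the second pECA26 feature in its highest single library. The residual was 35.1% for hisA, 14.1% for SYNPCC7002_RS09440 and 7.58% for SYNPCC7002_RS16700. For the rest of the 8 it was only 1.22% to 1.93%, close to the limit. Loss from every copy stays open for the other 18 members. Of these, 12 lay above 0.542%, that limit by group means, while the other 2 pECA26 features had 0 counts in the ccmR knockdown. The pECA26 limits gauge only reads out of place between libraries. Reads shared with copies elsewhere could leave a residual after full loss too, so full loss is not excluded for the 8 members. Such shared reads, a mixture of causes, a difference in strain history and an effect of the knockdowns stay open and untested.

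The second pattern is the set of 9 genes, SYNPCC7002_RS17310 left out, at least 4-fold lower in the ndhF3 ndhF4 knockdown outside that region. Of these, 7 lie in 2 runs on 1 strand each, SYNPCC7002_RS00855 to SYNPCC7002_RS00870 and SYNPCC7002_RS09045 to SYNPCC7002_RS09055. All 7 are lower than in the ccmR knockdown, where they also fell against control and were called. The medians there were -1.23 for the 4 genes of the first run and -0.51 for the 3 of the second. Library scaling is argued against in the ndhF3 ndhF4 knockdown. Its least fall in the runs was still -2.215 (log2) with scaling by total count. Repression of 2 groups of neighbouring genes is a candidate explanation that cannot be told apart from others, because the runs were picked for their fall and carry no gene names here.

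The third pattern is the fall of atpA and the next gene, SYNPCC7002_RS03655, in the ccmR knockdown. An equal change of the 8 genes of the row is argued against by Cochran's Q over its degrees of freedom, 88.638, and with scaling by total count the log2 fold changes were still -2.58 (atpA) and -3.50. The largest step between neighbours was 1.866 (log2), but the bounds for a block inside the row were set with these values in view, so that explanation is untested. Loss of transcript ends stays open, since the next gene of that strand, psb29, at 0.123 (log2), is a single gene. No biological explanation was tested.

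Splits of the 6 libraries of 2 groups number 10, too few for a share under 0.05. Every split but the real one mixes libraries of both groups, so a difference between the groups widens the spread within each mixed group. Fewer gene calls are thereby built in, and the contrast of gene counts is no support. The ccmR knockdown against control gave 1240 genes and the highest other split 0 (1 split as large, the real one included). For nhaS3 overexpression against control these were 83 and 0 (1 split), and for the ccmR knockdown against nhaS3 overexpression 1435 and 0 (1 split). For gene lists the ccmR knockdown gave 10 and the highest other split 11 (3 splits as large), and nhaS3 overexpression 13 and 14 (4 splits as large). Among splits parting all 3 title numbers the highest other values were 6 and 13.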

How the results depend on the processing

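Scaling by total count, leaving out the 3 libraries numbered 3 and leaving out the hisA region were chosen after seeing the data. Of 3979 alternative values of 216 results for named genes, 3753 kept the side of the threshold, 194 lost the call and 31 gained it. For 1 called gene the direction turned: gltB in the ccmR knockdown was at 0.0282 (log2) with scaling by total count (adjusted p = 0.82). Direction was followed only for genes called in the main test, so changes of sign in uncalled genes are not counted as turned. In all, 145 of the 216 were kept under every alternative run. The cause was not tested for any change below.

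With a threshold of 2-fold the counts were 138 (ccmR knockdown), 139 (ndhF3 ndhF4 knockdown), 34 (nhaS3 overexpression), 117 (ccmR against ndhF3 ndhF4 knockdown), 149 (ccmR knockdown against nhaS3 overexpression) and 154 (ndhF3 ndhF4 knockdown against nhaS3 overexpression), and the shared counts 57, 5 and 4. For nhaS3 overexpression DESeq2 gave 149 genes, the replicate block 188 (titles) and 126 (library names), and leaving out the 3 libraries numbered 3 gave 160. With DESeq2 the ccmR knockdown shared 46 and the ndhF3 ndhF4 knockdown 42 genes with nhaS3 overexpression. The block moved no other count of genes or lists by over 1.5 times, and it was not run for the shared counts. With an estimated correlation 1, 0 and 1 lists passed in the ccmR knockdown, ndhF3 ndhF4 knockdown and nhaS3 overexpression, against 10, 3 and 13. The 1 in nhaS3 overexpression was construct parts, which hold the introduced construct itself. With fry, which tests whether a list's genes move 1 way on balance, 12 passed in the ndhF3 ndhF4 knockdown and 1 in nhaS3 overexpression, and without the 3 libraries numbered 3 the ndhF3 ndhF4 knockdown had 5.

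Without each library in turn the counts of genes ranged from 960 to 1202 (ccmR knockdown), 655 to 1056 (ndhF3 ndhF4 knockdown), 45 to 73 (nhaS3 overexpression), 328 to 760 (ccmR against ndhF3 ndhF4 knockdown), 1177 to 1370 (ccmR knockdown against nhaS3 overexpression) and 781 to 1176 (ndhF3 ndhF4 knockdown against nhaS3 overexpression). Lists ranged from 8 to 12, 3 to 5 (5 without control replicate 3) and 8 to 14 (8 without nhaS3 overexpression replicate 1). Leaving out a library of the ndhF3 ndhF4 knockdown leaves 1, which is assumed to vary like the other groups.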

Other observations

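The runs of neighbouring genes were looked for after the data were seen. In the ccmR knockdown 11 runs of at least 3 neighbouring genes changed at least 2-fold in 1 direction, holding 73 of 136 such genes, against at most 2 runs in 1000 shuffles of gene order. The longest run, the 26 features of the hisA region, had a permutation p of 0.001, the smallest these shuffles can give. Shuffling treats neighbours as independent, which genes transcribed together are not. These values therefore show only that changed genes lie together. One run of 8 genes begins with bicA (2452833 to 2460377) and had a median log2 fold change of 1.22, with medians of -0.46 in the ndhF3 ndhF4 knockdown and -0.24 in nhaS3 overexpression. A run of 5 genes with cpcA (2300607 to 2304074) had a median of -1.78, and a run of 3 from hemN to acsF_RS09945 (2071309 to 2074721) a median of -1.20. A run of 8 genes at 1881910 to 1888648 had a median of -1.32 in the ccmR knockdown and -0.95 in the ndhF3 ndhF4 knockdown, where all 8 were also called. A run of 3 from SYNPCC7002_RS00850 to SYNPCC7002_RS00860 (178297 to 182762) had a median of -1.40 in the ccmR knockdown. In the ndhF3 ndhF4 knockdown the median of these 3 was -2.55, and 2 of them were called.

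In the ndhF3 ndhF4 knockdown there were 12 runs. A run of 6 genes on plasmid NC_010479.1 (2617 to 4884) had a median of 1.82 and one of 4 genes on NC_010480.1 (35841 to 39776) a median of 2.07, with 0 of these genes called in the ccmR knockdown or in nhaS3 overexpression. In nhaS3 overexpression a run of 6 genes with nthA and nthB (3673 to 7717 on NC_010478.1) had a median of 1.05. It leans on replicate 1, where nthA was at 356 CPM against 211 and 175, and nthB at 285 against 172 and 143. A run of 3 at 319181 to 321059 had a median of -1.84, with -1.01 in the ccmR knockdown and 0.93 in the ndhF3 ndhF4 knockdown.

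Within the hisA region the 11 genes from 1958435 to 1966906 rose in nhaS3 overexpression by 1.41 to 1.95, with a median of 1.62, and the other 15 had a median of 0.50. The point of division was chosen after these values were seen.

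Families of genes sharing the first 3 letters of a symbol and not in any list were tested with camera in each strain against control: 58 families, 0 of which had an adjusted p under 0.05 in any strain. At an unadjusted p under 0.05 there were 3 in the ccmR knockdown, 6 in the ndhF3 ndhF4 knockdown and 8 in nhaS3 overexpression, and the lowest adjusted p were 0.791, 0.250 and 0.261.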
